A study of Mus musculus with 2 samples.

How the data were processed

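The series holds 2 ChIP-seq libraries from C2C12 cells, a mouse myoblast line that can form muscle fibres in culture. Per the labels, the cells were infected for 6 h with a retrovirus that carries SYT-SSX2, a fusion protein of synovial sarcoma, with HA and FLAG tags. Chromatin was collected 48 h after infection. Per the labels, 1 library came from anti-FLAG immunoprecipitation and 1 from immunoprecipitation with control IgG. The FLAG library pooled DNA of 2 ChIP experiments, each on lysates of 2 infections, and the IgG library used pooled lysates of 2 infections. Each group therefore had 1 library, and no value below has a replicate error.

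Reads were aligned with Bowtie, per the submitters' processing notes. Peaks were called with MACS on the FLAG library against a control library, per the file headers, which name no antibody for the control. It was taken to be the IgG library, the other library of the series. The headers give a tag size of 43 bp, a band width of 300, a model fold of 32, a p cutoff of 1e-05 and an effective genome size of 2.7 Gb. They also give a fragment size d of 80 bp and local background ranges of 1000, 5000 and 10000 bp beside the peak region. The versions of Bowtie and MACS and the genome build are not given in the sources used here.

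Of the FLAG library's 29883377 tags, 19148901 (64.1%, 95% Wilson interval 64.06 to 64.1) were unique, per the file headers. The control library had 31208988 tags, of which 16806943 (53.9%, 53.84 to 53.87) were unique. PCR copies without molecular identifiers are not independent molecules, so these and later intervals cover counting error only. Both deposited lists of the FLAG library were used, and their 52992 peaks matched line for line in position and score. Per-position signal of either library was not used here.

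Each peak has 4 kinds of value besides its position. The tag count in each peak is a whole-number count without normalization, per the file headers and the values. The score in the authors' deposited lists is 10 times the −log10 of MACS's p-value, and it is at least 50 at the cutoff used. The fold enrichment is a ratio that MACS computed for the authors, from the height of the peak's pile-up and the local background. The FDR in percent is the authors' deposited value from MACS. All of these are the authors' own values. They served to describe, rank, filter and compare peaks within this list and to calculate and check a local background, as given below.

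Whether the available gene table, of assembly GRCm38, could be used with the coordinates was checked. The criteria fixed beforehand named chromosome ends, runs of unknown bases and gene starts. In place of the first and last, the last gene and both gene ends in the table were used. Runs of unknown bases were not checked. Of the peaks, 519 started beyond the last gene of their chromosome in that table, 501 of them on chromosome 7. Midpoints within 1 kb of an end of a protein-coding gene made up 4.07% of peaks at the deposited coordinates. They made up 4.09% after a shift of 100 kb to the right and 4.21% after a shift of 100 kb to the left. The check failed, so the reserve plan fixed beforehand was followed, which covers number, widths, scores, spacing and chromosome shares. Distances to genes, gene lists, GC content, repeats, motifs and the naming of genes were left out. Coordinates are given 1-based, in the build of the deposited lists.

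The rule fixed beforehand for naming items named the genes nearest to the 10 peaks with the highest score. With genes left out, those 10 peaks are given by position, ties in score being ordered by width. Merged domains are given by covered bases, and the windows with the most peaks were chosen after their values were seen, as were the peaks with the highest fold and the most tags. Peaks at most 5 kb apart were merged into domains.

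Without chromosome lengths or gap positions, the length of a chromosome was taken as the span from its first to its last peak. This differs from the plan, which named lengths without gaps. Shares of peaks have exact binomial (Clopper-Pearson) 95% intervals. For spacing, the peaks were placed at random 1000 times within the span of their own chromosome with their widths kept. The one-sided permutation p-value was doubled, so the smallest possible value was 0.002. For windows of 1 Mb, 100 placements were drawn, with a smallest possible value of 0.02. Medians of peaks with and without a near neighbour were compared with a two-sided permutation test of 100000 resamples and Benjamini-Hochberg adjustment over 4 measures. Peaks within 1 library are not independent replicates, so these p-values describe the arrangement within this list. Ratios of background have 95% bootstrap intervals from 1000 draws of whole 1 Mb windows. To compare empty windows at matched density, the peaks of X were thinned at random to the density of each autosome, 100 times each. The correlation of background with density across chromosomes was tested with two-sided permutation tests of 100000 resamples.

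The local background of each peak was calculated back from its tags, score and width, since MACS's score is a Poisson tail probability of the tags given that background. Lengths under 160 bp or over 1000 bp were set to those bounds. The tags were not cut to match, so the calculated background of peaks over 1000 bp may be too high. For some wide peaks it exceeded the peak's own tag density. The calculation was checked with the deposited fold, since fold times background must be the whole-number height of the pile-up. For 52938 peaks the calculation gave a value, and for 32693 of them (61.8%) the height was whole within 0.02 plus 0.005 times the background, against 4.99% expected by chance. Among peaks of at most 300 bp, 91.9% gave a whole height. Only peaks with a whole height entered comparisons of background between chromosomes or windows. Of 185 peaks with a calculated background over 10 times the genome-wide value, 73 gave a whole height. For 6 of those 185 the tolerance was at least 0.5, where any height passes, so very high backgrounds are not checked. Values are given as multiples of the genome-wide background of 0.567 tags per 80 bp.

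Both calculations were tested on simulated data. For spacing, the placement test called 0 of 40 sets of 5000 uniformly placed peaks and 40 of 40 sets in which some peaks had been placed beside others. Across 32149 simulated peaks, the background came back within 1% of the true value in 99.5%. Their scores were made with the same formula and length bounds, so this checks the arithmetic only and not whether MACS used that formula. Heights were whole for 100% of the simulated peaks, against 61.8% in the data, so the formula may not hold for many real peaks.

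Alternatives fixed before the data were examined were the 50% and the 10% of peaks with the highest score, a neighbour distance of 20 kb, and merge distances of 1 and 20 kb. Limits on FDR and fold, merged counting, placements within windows and all windowed results were added afterwards, as were the comparison of peaks with and without neighbours and the background calculation. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.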

Results

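SYT-SSX2 joins most of SYT, a subunit of SWI/SNF chromatin remodelling complexes, to the C-terminal part of SSX2, a nuclear protein. The series asked where in the genome this fusion protein resided when expressed in C2C12 mouse myoblasts. Sites were mapped by anti-FLAG ChIP-seq in 1 pooled library, with 19148901 unique tags, against 1 control IgG library with 16806943. Without replicates, no difference below was compared with a spread between cultures.

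The called SYT-SSX2 peaks were numerous, mostly narrow and unevenly spread over 20 chromosomes, 1 to 19 and X. Some calls adjoined each other, such as those on chromosome 4 from 152180658 to 152180917 and from 152180919 to 152181315. A called peak therefore need not be a separate site. The list held 52992 peaks, which covered 25.65 Mb, or 0.95% of the effective genome size. They held 1668593 tags, 8.71% of the unique tags of the FLAG library. The median peak was 366 bp wide and held 19 tags at a fold enrichment of 10.5 over the local background. From the 10th to the 90th percentile, widths ran from 228 to 815 bp, tags from 10 to 51, and fold enrichment from 7.16 to 15.7. The upper end was long, with 612 peaks wider than 2000 bp and 1459 with a fold over 20. MACS gave 35413 peaks (66.8%) an FDR of at most 1%, and the highest FDR of any peak was 2.82%. The median score was 74.9, against a minimum of 50, so many peaks lay near the calling threshold.

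The chromosomes differed widely in peak density, and X stood first. X carried 9750 peaks, or 18.4% of all (95% exact interval 18.07 to 18.7), in 6.43% of the total span. Its density of 59.6 peaks per Mb (58.5 to 60.7) was 2.86 times that of all chromosomes together and 4.52 times that of the median autosome. Chromosome 4 came second with 6309 peaks, at 41.4 per Mb (40.4 to 42.4), or 1.99 times the value of all chromosomes. Chromosome 3 had the lowest density, with 674 peaks at 4.37 per Mb (4.05 to 4.71), and X exceeded it 13.6 times. When peaks at most 5 kb apart were counted as 1, X still stood first, at 3.09 times the density of all chromosomes, and exceeded chromosome 3 by 7.12 times. In that count chromosome 4 fell to 0.919 times the density of all chromosomes, and chromosome 11 was second with 1.39 times.

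Behind X and 4, chromosome 15 had 31.9 peaks per Mb, chromosome 11 had 31.5, chromosome 2 had 29.9 and chromosome 5 had 28.1. Chromosomes 12, 8 and 17 lay near the value of all chromosomes, 20.8 per Mb, with 22, 21.6 and 21.3. The other 11 chromosomes lay below it, from 13.8 per Mb on chromosome 19 down to 8.42 on chromosome 16, 6.22 on chromosome 10 and 4.37 on chromosome 3. X, 4, 2, 5 and 11 together held 55.2% of the peaks in 29.8% of the span. Chromosomes 3, 10 and 16 held 4.22% in 14.6%. Among the 10% of peaks with the highest score, chromosome 4 stood first with 3.01 times the density of all chromosomes, and X was second with 2.64 times. Among peaks with a fold of at least 10, chromosome 15 fell from 1.53 to 0.934 times the density of all chromosomes. The intervals cover counting error only, and since peaks lay in groups they are narrower than an interval over independent regions.

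**Figure D1:**
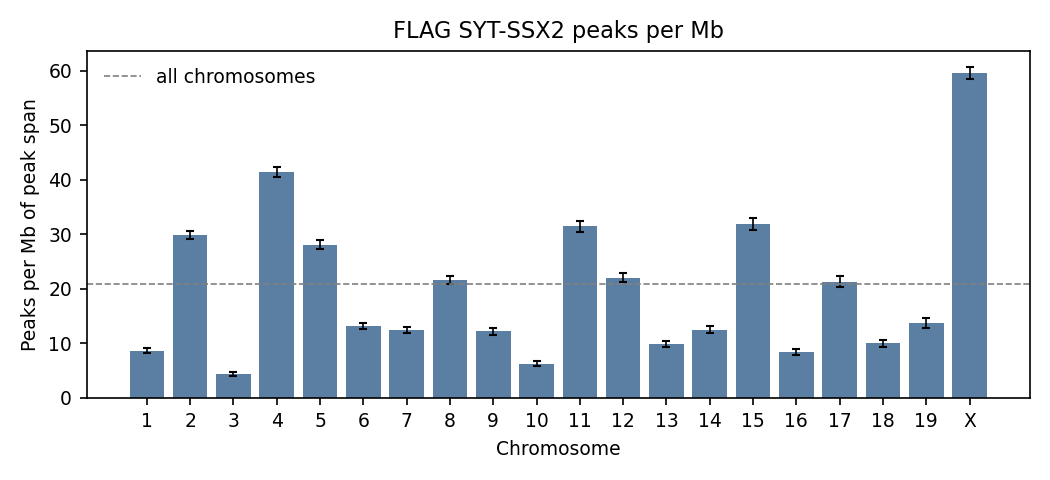
Peaks per Mb of each chromosome's span from first to last peak, for the 52992 peaks of the FLAG SYT-SSX2 library. Bars start at 0, whiskers are exact binomial 95% intervals for counting error, and the dashed line is the density over all chromosomes, 20.8 per Mb; X (59.6) and 4 (41.4) stand highest and 3 (4.37) lowest.

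Fold enrichment was highest on chromosome 4, and peaks were widest on chromosome 15. The median fold on chromosome 4 was 12, against 10.6 on X and 8.92 on chromosome 15, the lowest. The median width on chromosome 15 was 466 bp, against 378 bp on chromosome 4 and 348 bp on X. Peaks covered 29422 bp per Mb of X, 20644 bp per Mb of chromosome 4, 19792 bp per Mb of chromosome 15 and 1839 bp per Mb of chromosome 3. The implied local background was taken only from peaks with a whole height. These were 1525 of 3202 peaks on chromosome 15, 3630 of 6309 on chromosome 4 and 6124 of 9750 on X. Its median was 1.77 times the genome-wide value on chromosome 15, 1.16 times on chromosome 4 and 1.25 times on X. These differences were not tested.

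Within chromosomes, the peaks were concentrated in a small part of the sequence. In windows of 1 Mb, the densest 10%, or 256 of 2561 windows, held 35720 peaks, 67.4% of all. Random placement of the peaks within their chromosomes put 26.4% in the densest 10% on average and at most 26.5% (permutation p = 0.02, the smallest that 100 placements can give). The median window held 2 peaks, and 806 windows (31.5%) held none, against at most 9 after random placement. The placements did not avoid assembly gaps and moved each call on its own, so part of these contrasts may come from that. Every chromosome had at least 1 of the dense windows, which held 56 peaks or more. X had 54 of them, chromosome 5 had 26, chromosomes 2 and 4 had 25 each, chromosome 11 had 17 and chromosome 3 had 1.

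The window with the most peaks lay on chromosome 4 from 152 to 153 Mb, with 874 peaks that covered 453 kb of it at a median fold of 14.0. Its neighbour from 153 to 154 Mb held 748 peaks at a median fold of 12.3. These 2 windows carried 13.9% and 11.9% of the peaks of chromosome 4, which had another 527 from 139 to 140 Mb. On X, the fullest window, from 7 to 8 Mb, held 601 peaks at a median fold of 11.9, or 6.16% of that chromosome's peaks. Chromosome 5 had 514 peaks from 113 to 114 Mb, chromosome 15 had 451 from 87 to 88 Mb and chromosome 11 had 402 from 114 to 115 Mb. Chromosome 2 had 448 peaks from 179 to 180 Mb, 389 from 172 to 173 Mb and 372 from 180 to 181 Mb. The highest count in any window after random placement was 91.

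**Figure D2:**
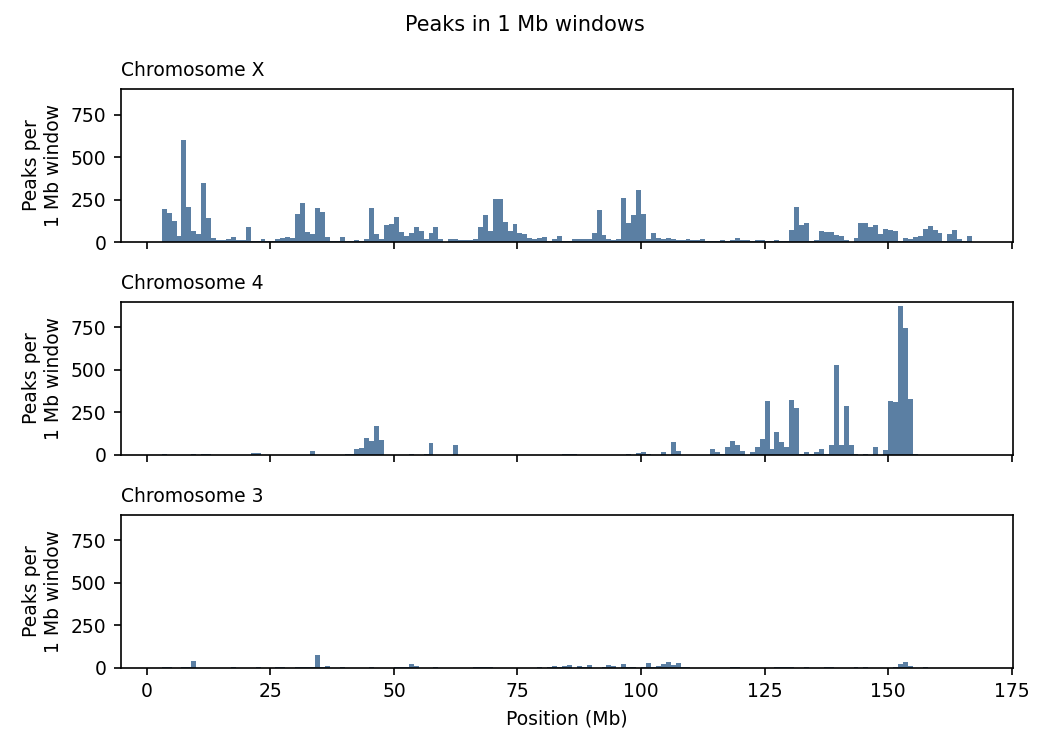
Number of SYT-SSX2 peaks in consecutive 1 Mb windows along chromosomes X, 4 and 3, with position in Mb on the horizontal axis and the same vertical scale in each panel. Chromosome 4 rises to 874 and 748 peaks in the windows that start at 152 and 153 Mb, X reaches 601 in the window from 7 to 8 Mb and has peaks in all of its 164 windows, and no window of chromosome 3 holds more than 76.

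At short range, called SYT-SSX2 peaks lay next to each other far more often than random placement gave. Adjoining calls of 1 broad region count as neighbours here, so a high share does not show that separate sites lie close together. Another peak midpoint lay within 5 kb of 81.6% of the peaks, against 25.5% ± 0.227 (SD over 1000 random placements), or 3.19 times as many. The highest of the placements gave 26.3% (permutation p = 0.002, the smallest that 1000 placements can give). When peaks were placed only within their own 1 Mb window, 59.6% had such a neighbour, and at most 60.3% (permutation p = 0.002, again the smallest possible). The share with a neighbour was 92.3% on chromosome 4, 88.9% on 15, 87.4% on 2, 84.2% on 11 and 81.2% on X. It was lowest on chromosome 3, at 54.5%, and on chromosome 10, at 66.9%.

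Peaks with a near neighbour were wider and richer in tags than isolated peaks, while their fold differed little. The 43219 peaks with a neighbour within 5 kb had a median width of 387 bp, against 295 bp for the other 9773. Their median tag number was 20 against 14, and their median score was 78.6 against 62.9. Median fold was 10.6 against 10.2, a difference of 0.37. Each of the 4 differences had an adjusted permutation p of 1e-05, the smallest that 100000 resamples can give. Peaks of 1 library are not independent, so these p-values are smaller than the evidence from separate regions would give.

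Merging peaks at most 5 kb apart gave 15780 regions, of which 9298 were single peaks. The other 6482 held 2 or more peaks, and 82.5% of all peaks. Domains of 10 or more peaks numbered 970 and held 24512 peaks, 46.3% of the list. X had 161 of these large domains, chromosome 2 had 122, chromosome 4 had 102, chromosome 15 had 85 and chromosome 3 had 1.

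The 4 domains with the most bases under peaks all lay on chromosome 4. The first, from 153539682 to 154055601, spanned 515.9 kb and held 480 peaks that covered 274 kb, or 53.2%, at a median fold of 12.9. The second, from 151772179 to 152116730, held 275 peaks over 345 kb, covered to 71.9%, at a median fold of 15.6. The third, from 152526948 to 152892446, held 343 peaks, and the fourth, from 139784175 to 140065704, held 237. Their median folds were 14.1 and 12.8. The order depended on the merging, since the first came from the place of the second in other settings. It ran from 151788689 to 151961450 with merging up to 1 kb and from 151714166 to 153331388 with merging up to 20 kb, and it started at 151790004 among the 50% of peaks with the highest score. On X, the domain from 7120208 to 7438773 held 242 peaks over 319 kb at a median fold of 11.3. Other domains of X lay from 99874255 to 100077471, from 7688081 to 7882243 and from 11621473 to 11807361, with 134, 162 and 142 peaks. On chromosome 6, the domain from 114420100 to 114587783 was covered to 89.4% by 79 peaks at a median fold of 17.6. The domain of chromosome 8 from 126061065 to 126153525 held 3 peaks with 37278 tags, nearly all in a pair of wide ones.

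**Figure D3:**
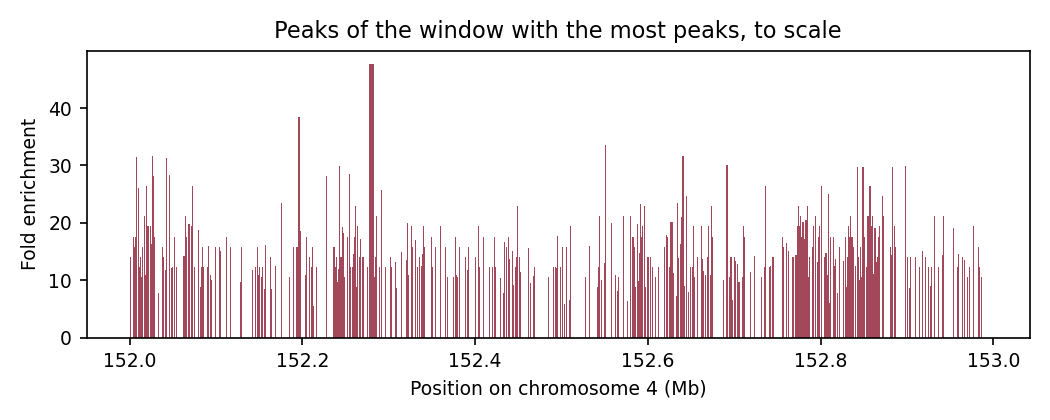
Fold enrichment of each peak on chromosome 4 between 152 and 153 Mb, the window with the most peaks. Each of the 874 bars spans its peak from start to end to scale, the vertical axis starts at 0, and the median fold is 14.0.

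Of the 10 peaks with the highest score, 5 lay above the value of 3100 at which 44 peaks were tied. So many ties at 1 value may mark a limit of the score. The order of the peaks at and above 3100 is therefore not read as a ranking of strength. On chromosome 8, the peak from 57993999 to 57999897 had a score of 3233 with 1175 tags and a fold of 16.7. A peak on chromosome 13 from 58447527 to 58451462 scored 3230 at a fold of 14.3, and a peak on chromosome 7 from 28880605 to 28883751 scored 3165 at a fold of 16.7. Chromosome 4 had the next pair, from 151841980 to 151847642 and from 151860833 to 151865365, with scores of 3139 and 3121 and folds of 33.5 and 35.3. Both lay inside the second of the chromosome 4 domains above. The widest of the tied peaks lay on chromosome 8 from 126061065 to 126124281, with 26209 tags over 63.2 kb at a fold of 27.1. The next, from 126124311 to 126148568, adjoined it with 11052 tags at a fold of 16.3. Chromosome 1 had a peak of 23.5 kb from 172992998 to 173016514, with 14701 tags at a fold of 31.2. A peak of 19.7 kb on chromosome 10 from 57683429 to 57703108 and a peak of 18.7 kb on X from 131574318 to 131593056 had folds of 12.4 and 11.7.

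Fold enrichment ranked other sites first. The highest fold, 110.9, belonged to a peak of 1831 bp on chromosome 18 from 83712198 to 83714028, with 697 tags and a score of 3100. A peak on chromosome 9 from 21754760 to 21755219 had a fold of 94.9 with 88 tags, and a peak on chromosome 2 from 32873536 to 32874010 had 82.1 with 84 tags. On chromosome 4, the peak from 139421512 to 139422915 reached 69.5 with 164 tags, and on chromosome 1 the peak from 83056657 to 83057322 reached 67.0 with 85 tags. The chromosome 18 peak was tied in score with the sixth to the 10th of the peaks ranked by score and stood behind them by width. The other 4 scored from 593 to 1108.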

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

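Limits on FDR and fold, merged counting, low background, placements within windows and every setting of the windowed result were chosen after the data had been seen. X stayed above the density of all chromosomes (2.86 times) in all 6 alternatives, at 2.73 times for the 50% of peaks with the highest score, 2.64 for the top 10% (where chromosome 4 led), 2.76 for FDR of at most 1%, 2.94 for a fold of at least 10 and 3.09 with merged peaks. Leaving out peaks with a calculated background over 10 times the genome-wide value, or a score from 3000 where no background could be solved, gave 2.86. The densest 10% of windows held 74.9%, 86.9%, 72.1% and 69.4% of the peaks in the first 4 of these settings, against 67.4%, then 72.8% in windows of 500 kb and 44.8% with merged peaks. Random placement was not run for the first 4 lists. A shorter list gives a larger share by its size alone, so no stronger concentration follows. The list shrank by construction to 26496 and 5299 peaks in the top 50% and 10% and to 29187 at a fold of at least 10. Domains of 2 or more peaks numbered 4067 with merging up to 20 kb and 3569 in the top 50%, against 6482. For other moved values, the cause was not tested. The share of peaks with a neighbour stayed above random placement in every setting run. Of 114 alternative densities of the other chromosomes, 104 stayed on their side of the density of all chromosomes, and 42 stayed within their interval. With merged peaks chromosome 4 crossed from 1.99 to 0.919 times, and chromosomes 8, 12 and 15 crossed to between 0.971 and 0.99. At a fold of at least 10, chromosomes 15, 8 and 17 crossed to 0.934, 0.96 and 0.862. In the top 10%, 8 and 17 crossed to 0.992 and 0.857, and in the top 50%, 17 crossed to 0.995. The domain with the most covered bases lay on chromosome 4 in each setting, but was another one with merging up to 1 or 20 kb and in the top 50%. Settings fixed beforehand on genes, gene starts, exons, GC, repeats, motifs and full chromosome lengths were not run. No paired analysis was possible because each group had 1 library. The median peak held 19 tags and the smallest number was 9; how depth limits the list was not tested.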

Other observations

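The tests of merged regions against random placement, of empty windows on X at matched density and of background across chromosomes were chosen after the results they bear on had been seen. The bounds of the other tests were set after the peak counts were known but before the values they apply to were computed. For copies of X, the ratio of background became the value compared with the bound after dividing by that ratio, which was below 1, had changed nothing.

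X had peaks along its whole length. None of the 164 windows of 1 Mb on X was empty, and the median X window held 25.5 peaks. On chromosome 11, the autosome with the highest median, the median window held 12 peaks and 24 of 119 windows were empty. Chromosome 4, second in peaks per Mb but not in merged regions per Mb, had a median of 1 peak per window and 60 empty windows of 153. Thinned at random to the density of chromosome 4, X had at most 0.61% empty windows in 100 draws, against 39.2% on chromosome 4. Thinned to the density of chromosome 3, X had at most 28.1%, against 36.8% there. That thinning kept only 716 of the 9750 X peaks and so broke up their groups, which leaves fewer windows empty by itself.

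A small number of peaks held very many tags. The 6 peaks with at least 7000 tags each, on chromosomes 8, 1, 10 and X, held 76089 tags, 4.56% of all tags in peaks, at 58.5 to 88.1 times the genome-wide tag density. On chromosome 8, the peaks from 126061065 to 126124281 and from 126124311 to 126148568 lay next to each other, and a further peak, from 56196771 to 56209098, held 7180 tags at a fold of 8.72. At the opposite end, a peak on chromosome 17 from 39979890 to 39985958 held 6602 tags at a fold of 1.95, the lowest in the list. In all, 185 peaks in 96 windows had a calculated background over 10 times the genome-wide value, with 5.66% of the tags, and the whole-height check held for 73 of them. The largest group of them lay on X from 166412376 to 166635665, with 23 peaks at a median fold of 5.65. A group of 15 lay on chromosome 6 from 47597705 to 47728527 at a median fold of 7.26. A group of 11 on the same chromosome, from 114446353 to 114570499, had a median fold of 17.0. For some wide peaks the calculated background is too high, since tags beyond 1000 bp were not cut. The X peak from 166428700 to 166447083 held 5207 tags over 18384 bp. Its calculated background of 373.7 tags per 80 bp exceeded its own tag density. These groups are therefore groups by calculated value and need not be regions of high background.

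The first pattern weighed was the high density of X. More copies of X in these cells would raise the background at its peaks. X had 0.951 times the autosomal background (95% bootstrap interval 0.91 to 0.9998), below the bound of 1.5 times. This argues only weakly against more copies. Only peaks with a whole height entered, 6124 of 9750 on X. The medians, 1.25 times the genome-wide value on X and 1.32 times on autosomes, lay close to that value. A lower limit there, taken up below, would hold the ratio toward 1. Without the densest 10% of each chromosome's windows, X kept 39.2 peaks per Mb (38.3 to 40.03), against 15.7 (14.99 to 16.4) on chromosome 11, the next. This cut lowers chromosomes with crowded peaks most, and it left in most of the 54 dense windows among the 164 of X. The rank after the cut therefore decides little. Still, X after the cut lay above every uncut autosome but chromosome 4, at 41.4, so its densest 10% of windows alone did not carry its high density. Thinned to the density of each autosome, X had fewer empty windows than that autosome in all 100 draws for 19 of 19, a measure which tests no cause. Thinning breaks up groups of peaks on X while those of the autosome stay whole, so fewer empty windows need not mean less clustering. This matters least for chromosome 4, for which 6773 of 9750 X peaks were kept. Mappability, GC content and unspecific binding of the FLAG antibody were not tested, and no biological explanation was tested.

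The second pattern was the crowding of peaks into few windows. Dividing out the background of the dense windows, 1.03 times (1 to 1.08) that of the others, left them with 11.5 times as many peaks per occupied window, against 12.1 before. This argues only weakly against copy number as the cause. The windows of chromosome 4 from 152 to 153 Mb and from 153 to 154 Mb had a median background of 0.567 tags per 80 bp, the genome-wide value. On chromosomes 4, 7 and 9 the lower quartile of background was also 1 times the genome-wide value, and no chromosome had a lower one. That points to a lower limit of the background, which holds ratios such as this and that of X toward 1. Splitting of broad regions into several peaks was tested with merged regions, for which the ratio was 4.09 (3.84 to 4.38). That ratio decides nothing, because merging lowers counts most where peaks are dense and randomly placed regions already gave 3.29 on average, over the bound of 2. Counted alone, 44.8% of the merged regions lay in the windows densest in them, against at most 27.3% after random placement. The permutation p was 0.02, the smallest possible with 100 placements. Splitting of regions with gaps up to the main merging distance therefore does not by itself account for the crowding. Broad regions with longer gaps still count as many, so the test cannot decide on them. With merging up to 20 kb, a region of chromosome 4 from 151714166 to 153331388 held 1316 peaks. The share was not computed at that distance. Whether splitting adds to the crowding stays open.

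The third pattern was the difference in density among chromosomes. If copy number set it, background would rise with density, and across the 20 chromosomes Spearman's rho was 0.0887 (permutation p = 0.71) and Pearson's r was -0.00945 (permutation p = 0.97), with an adjusted p of 0.97 for each over the 2 measures. Without chromosomes 15 and 10, the pair farthest from the median background, r was -0.0675 (permutation p = 0.79) and rho was 0.152. With 20 values, and with backgrounds held up by such a lower limit, a modest relation could go unseen. Copy number therefore stays open as a part of this pattern. Chromosome 15, with the highest background at 1.77 times the genome-wide value, and chromosome 10, at 1.62 times, had densities at opposite ends, 31.9 and 6.22 peaks per Mb.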
